A study of Mus musculus with 8 samples.

How the data were processed

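RNA of cultured mouse cells was hybridised to 8 Illumina BeadChips, arrays on which each probe sits on many small beads and the fluorescence of a bead measures the amount of the matching RNA. The labels give 4 groups of 2 arrays each: neural stem cells (NSCs) titled female (fNSC), parthenogenetic NSCs (pNSC), NSCs titled miPS-NSC, and mouse embryonic fibroblasts (MEF). Parthenogenetic cells come from an egg activated without sperm, so both of their genome copies are maternal. The labels do not explain miPS-NSC, which is read here, from the name and the series title, as NSCs differentiated from induced pluripotent stem (iPS) cells, and they do not say which cells these were made from. The sample names of these arrays read pips-NSC, beside PNSC for the pNSC arrays, and the labels do not explain that name either. The second array of each group has a title ending that the labels do not explain. Nothing says whether the arrays of a group came from separate cultures, so the p-values of single genes measure only the spread between these arrays, which may be technical. Group is tied to genotype and to a number in the sample name, since the labels give fNSC the genotype OG2ROSA with the number P27, and pNSC and miPS-NSC the genotype OG2+/- with P18 and P8. The labels also give MEF the genotype OG2+/-, whereas the column names of the signal table name OG2ROSA1 for the MEF arrays, and this disagreement was left open. The growth medium in the labels is the NSC medium for every group, MEF included.

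The signal table holds, per the file headers, the mean bead intensity of 25697 probes on each array, not background-subtracted and not normalized between arrays as far as its values show, with GenomeStudio 2009.2 named in the submitters' processing notes. Per the file headers it also gives the standard error of the intensity over the beads and the number of beads, whose median was 34 to 40 per probe. The deposited detection p-value of a probe moves in 798 steps, as the share of negative control probes brighter than the probe would. At a detection p under 0.01, between 10553 and 10902 probes (41.1% to 42.4%) were detected per array. The authors' processed values are on a log2 scale with identical quantiles on all 8 arrays, and cover 12421 probes. These are exactly the 12421 probes with a detection p under 0.05 on at least 4 of the 8 arrays, as tested on the signal table. Each authors' column correlated best with the signals of its own array (Pearson's r 0.9975 to 0.9999 across probes), so scale and direction are settled, while the background step before it is not given in the sources used here. The median authors' value was 9.119 on every array.

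Gene names came from the platform annotation of the authors' probes: 11692 probes had 1 symbol, 0 had several and 729 had none. Of these, 11686 were found by gene ID in a RefSeq table (assembly GRCm38.p6), and 0 symbols needed an update. Probes outside the authors' values have no name here. Because the authors' filter needed 4 arrays, a gene switched on in only 1 group of 2 arrays is mostly unnamed here. That gap removes group-specific genes from every count of genes, most of all those of MEF. Chromosomes were taken from the same RefSeq table, in which gene order was used only to sort genes along a chromosome. The build behind the probe design is not given in the sources used here.

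Signals were corrected and normalized with neqc of limma 3.58.1 (R 4.3.3, with the data.table package, version 1.17.8), which fits the background from the detection p-values, adds an offset of 16, takes log2 and equalises quantiles. A probe was kept when its detection p was under 0.01 on both arrays of at least 1 group, which left 12478 probes, 10958 of them with a gene and 1520 without (852 of these outside the authors' values). The brightest of a gene's kept probes stood for the gene, giving 8107 genes, 2095 of them with over 1 kept probe. The limma functions lmFit and eBayes were fitted to all 8 arrays at once (4 residual and 2.98 prior degrees of freedom). P-values are two-sided and adjusted by Benjamini-Hochberg over the 8107 genes, and a gene was called when its adjusted p was under 0.05 and its change at least 2-fold. A call did not require detection in the groups compared, so some called differences lie below background. Log2 values are given with the SD over 2 arrays and log2 differences with the limma standard error (SE). Where the dimmer group of a comparison was not detected on both of its arrays, the fold is written as "at least", the bright group's mean against the dim group's mean of, per array, the higher of the lowest normalized signal of a detected probe (6.13 to 6.29 on the log2 scale) and the probe's own value. No fold is given where neither group was detected on any array. The number of arrays limits the precision.

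A total of 20 gene lists was fixed before the data were examined: paternally and maternally expressed imprinted genes, neural stem cell markers, pluripotency, fibroblast and mesenchymal, astrocyte, neuron, oligodendrocyte lineage, neural crest, endoderm and mesoderm, microglia and blood, proliferation, forebrain regional, hindbrain and posterior regional genes, DNA methylation and imprint regulators, interferon response, MHC class I, oxidative stress and glutathione, X inactivation and Y-linked genes. Of these, 17 had at least 2 measured genes and were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 17 lists within a comparison, again with an estimated correlation, and with fry. The estimate was 0.00356 for paternally expressed genes and -0.0358 for neural stem cell markers. A larger p under that setting therefore does not by itself show that the genes of a list are correlated. Camera and Fisher's exact test set genes of a list against other genes, so their p-values do not measure the spread between cultures. List results below are those of camera unless fry is named. Fry sets a list against the spread between arrays, not against other genes. A list that did not pass camera can therefore have a small fry p and is not shown to be unchanged. The list of microglia and blood genes had no measured member, and the lists of endoderm and mesoderm genes and of Y-linked genes had 1 each. In every comparison the counts adjusted over the list alone equalled those adjusted over all genes. Imprinted genes not analysed here, for lack of a named probe that passed the filter, include Peg3, Plagl1, Magel2, Zrsr1, H19, Meg3 and Grb10.

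The genes named were chosen by a rule fixed before the data were examined. It took the 5 largest fitted rises and falls among called genes in each comparison of NSC groups (4 against MEF), every called imprinted gene, a fixed set of imprinted genes whatever their result, and up to 4 called members of each other list, or up to 2 with the smallest p where none was called. The text names part of these. Outside the rule, Peg10, Inpp5f, Mkrn3 and Nap1l5 are also given in comparisons in which they were not called, and were chosen after their values were seen. The comparisons were pNSC against fNSC, miPS-NSC against pNSC, miPS-NSC against fNSC, and the mean of the 3 NSC groups against MEF. Alternatives were other normalizations, the authors' values, other detection filters, the mean of a gene's probes, other thresholds, other fits and leaving out each array. The fit was tested on simulated data for pNSC against fNSC with 8107 genes: of 50 genes changed at each size, 0 were called at 1.5-fold, 24 at 2-fold, 50 at 4-fold and 50 at 8-fold, and 0 of 7907 unchanged genes were called. The 2-fold minimum holds back the smaller sizes, as 27 genes at 1.5-fold and 45 at 2-fold passed the adjusted p alone. Noise was drawn independently for each gene and array, so differences between cultures were not simulated. Figures were drawn with matplotlib 3.10.9. No probe sequences were used here.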

Results

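Gene expression was measured in 3 kinds of cultured mouse neural stem cells and in embryonic fibroblasts, with 2 arrays per group and 8 arrays in all. The fNSC and pNSC groups differ in the origin of their genomes, since parthenogenetic cells lack a paternal copy. The miPS-NSC group is read here, from its name and the series title, as neural stem cells differentiated from iPS cells, which are made by reprogramming other cells. Imprinted genes are read from only the maternal or only the paternal copy, so the comparisons of the 3 NSC groups ask how imprinted genes and the rest of the transcriptome stand in pNSC and in miPS-NSC. The arrays of a group never held identical values, and the difference between them exceeded the noise among beads (chi-square per probe 1.43 to 2.2). Bead noise is only part of technical noise, so this does not tell separate samples from 1 sample hybridised again, and the fit took them as 2 samples. Between 10553 and 10902 of the 25697 probes were detected per array. The SD of the log2 difference between the arrays of a pair was 0.261 in fNSC, 0.258 in pNSC, 0.252 in miPS-NSC and 0.164 in MEF.

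The 3 NSC groups lay closer to each other than to MEF. Over 8107 genes, the root mean square log2 difference was 0.818 between fNSC and pNSC, 0.888 between fNSC and miPS-NSC, and 0.892 between pNSC and miPS-NSC. The distances to MEF were 1.72, 1.69 and 1.67, against 0.164 to 0.261 between the arrays of a pair. The distances among the NSC groups shrank to 0.528, 0.581 and 0.587 with the authors' processed values.

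Paternally expressed imprinted genes were nearly silent in pNSC. Of the 11 measured members of the list, 7 fell against fNSC, and all 7 were detected on both fNSC arrays and on neither pNSC array. Mest, a gene of the hydrolase family, dropped from 13.42 ± 0.3 to 4.9 ± 0.03 (log2 mean ± SD, n = 2), at least 148-fold (log2 difference -8.53, SE 0.185). Snrpn, a spliceosome component of the Prader-Willi region, was at least 90.9-fold lower, with another Snrpn probe at -1.98 on the log2 scale. Impact was lower by at least 20.2-fold, Nnat by at least 11.8-fold, Mkrn3 by at least 11.4-fold, Nap1l5 by at least 11.3-fold and Ndn by at least 10.2-fold. The limma adjusted p of these 7 genes lay between 4.02e-08 and 1.52e-06. The remaining members were not called: Igf2, Dlk1 and Peg10 were below background in both groups, and Inpp5f stood at 11.71 ± 0.03 in fNSC and 10.84 ± 0.2 in pNSC. None of the 7 genes lies on chromosome 4 or 19.

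**Figure D1:**
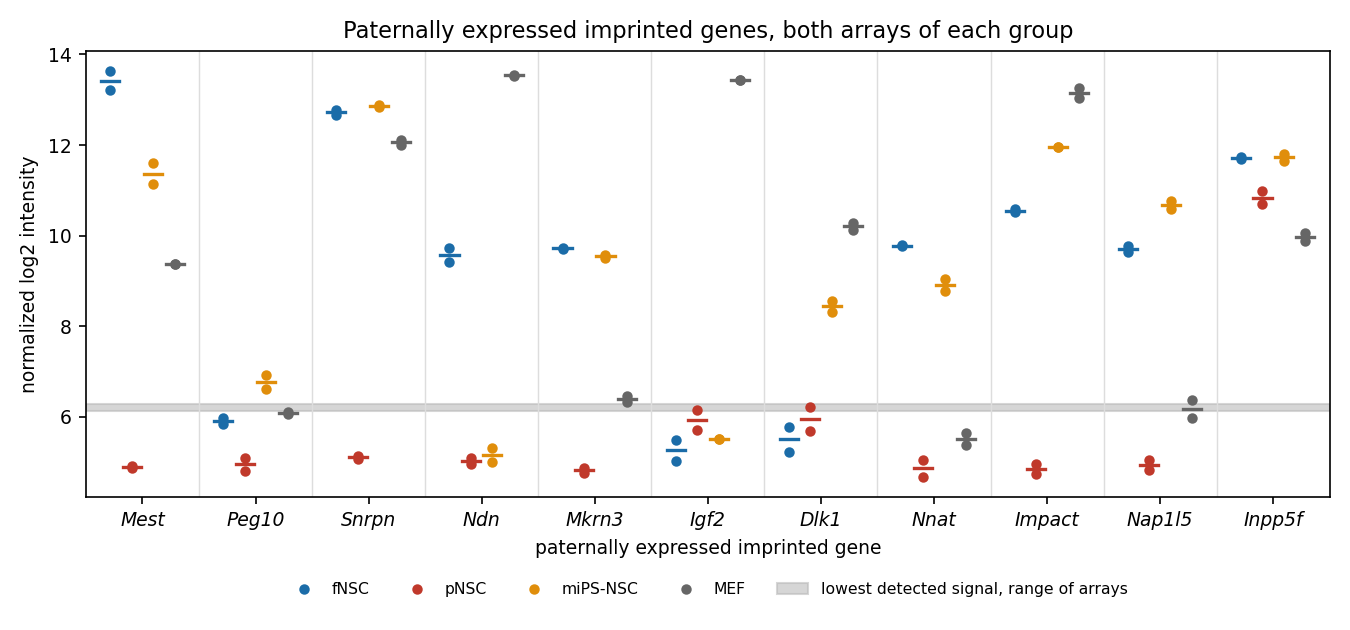
Normalized log2 intensity (vertical axis) of the 11 measured paternally expressed imprinted genes (horizontal axis) on each array, with points for arrays and short bars for the mean of 2 arrays per group, and a grey band for the lowest detected signal of the arrays. In pNSC, the means of 10 of the 11 genes lie under the band, and 6 of the 7 that fell against fNSC are high again in miPS-NSC, while Ndn stays at 5.17.

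The median log2 difference of the list was -4.77 between pNSC and fNSC, or -3.5 with below-background genes set at their bounds (camera, adjusted p = 4.72e-06, and adjusted p = 0.103 with an estimated correlation). It was -2.41 with the authors' processed values, which cover 13 members. Adjusted over the list alone, 7 genes were again lower and 0 higher. Lower calls took 63.6% of this list and 4.79% of the other 8096 genes (7 of 11 against 388, Fisher's exact test, two-sided, p = 1.72e-07). That test counts genes as independent, though Snrpn, Mkrn3 and Ndn share the Prader-Willi region. The 15 measured maternally expressed genes had a median difference of 0.116 (0.046 at the bounds) and did not pass the test as a list (adjusted p = 0.535). Whether each of these genes is imprinted in these cells was not tested, so the list result says little about maternal copies. Among the 15 genes Cdkn1c, a cyclin-dependent kinase inhibitor, fell 2.32-fold and Gatm, a creatine synthesis enzyme, rose at least 1.6-fold. Igf2r, the clearance receptor of insulin-like growth factor 2, was at 9.87 ± 0.24 in fNSC and 9.98 ± 0.05 in pNSC and was not called.

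Outside the imprinted genes, astrocyte genes were higher in pNSC than in fNSC. They rose as a list (3 of 7 members higher, median 0.885, camera adjusted p = 0.00944, and adjusted p = 0.295 with an estimated correlation). Apoe, a lipid carrier of the brain, rose at least 35.9-fold (log2 difference 5.62, SE 0.19), Gja1, the main astrocyte gap junction protein, 17.9-fold and Clu, a secreted chaperone, 8.13-fold. Lpl, lipoprotein lipase, rose at least 93.3-fold over an fNSC level detected on 1 array, beside Scara3 (at least 40.3-fold), the oxysterol hydroxylase Cyp7b1 (at least 29-fold) and Pdgfra, a receptor of oligodendrocyte precursors and fibroblasts (at least 25.9-fold). Outside imprinted genes, Sspn, a member of the dystrophin complex, fell at least 26.1-fold and Vxn 54.2-fold. Ifitm3, an interferon-induced membrane protein, fell 27.2-fold, although 6 of the 7 measured interferon response genes were not called. Glutathione genes Gsta4 and Gstm1 rose 3.17-fold and 2.33-fold, and their list did not pass the test (3 of 11 higher, adjusted p = 0.0516).

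Few neural stem cell markers were called between pNSC and fNSC. Of 18 neural stem cell markers only Hes5, a Notch target, was called, lower by 2.72-fold. Of 9 hindbrain and posterior genes, Gbx2 was lower by 4.95-fold and Hoxa4 (3.04-fold) and En1 (at least 2.33-fold) were higher, and of 4 forebrain genes Otx2 was higher by at least 2.47-fold. Dnmt3b, a de novo DNA methyltransferase, fell 2.85-fold and Ctcfl at least 2.05-fold, while 11 other imprint regulators were not called. In the proliferation list Cdc20 fell 2.35-fold and Cdkn2a, an inhibitor of the cell cycle, at least 6.14-fold to a pNSC level detected on 1 array, with another Cdkn2a probe at -1.06 on the log2 scale, and 15 members were not called. Neuron genes gave 2 higher and 1 lower of 7, fibroblast genes 2 higher and 1 lower of 11, and oligodendrocyte lineage genes 1 higher of 3. No neural crest, MHC class I, X inactivation or Y-linked gene was called, 1 of 6 pluripotency genes was lower (Klf4, at least 1.33-fold, with its other probes between -0.618 and 0.025 on the log2 scale), and Gata6 was the only measured endoderm and mesoderm gene and rose at least 1.8-fold. None of these lists passed camera (adjusted p between 0.114 and 0.831), and for neural stem cell markers, pluripotency, proliferation, hindbrain and interferon genes the median and the mean had opposite signs, the test going with the median.

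In all, 928 of 8107 genes were called between pNSC and fNSC, 533 higher and 395 lower in pNSC. Of the lower genes, 112 lie on chromosome 4, Hes5, Klf4, Cdkn2a and Cdc20 among them, and 36 on chromosome 19. Leaving out both chromosomes, an alternative chosen after seeing the data, gave 511 higher and 247 lower. The count fell to 446 with the authors' processed values and to 412 with quantile normalization without background correction.

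Most of the paternally expressed genes that were low in pNSC were measured again in miPS-NSC. Against pNSC, 8 of the 11 list members rose. Snrpn was at least 101-fold higher (the other probe at 2.09 on the log2 scale), Impact at least 53.9-fold, Mest at least 35.6-fold, Nap1l5 at least 22-fold, Mkrn3 at least 10-fold and Nnat at least 6.47-fold. Dlk1, a Notch ligand-like gene that neither fNSC nor pNSC showed above background, rose at least 4.69-fold, and Peg10 at least 1.48-fold. Ndn, a neighbour of Mkrn3 and Snrpn in the Prader-Willi region, stood at 5.02 ± 0.1 in pNSC and 5.17 ± 0.22 in miPS-NSC, below background in both, on the only probe with its name. Igf2 was likewise below background in all 3 NSC groups. The list median was 4.04, or 2.69 at the bounds (camera, adjusted p = 3.76e-06, and adjusted p = 0.1 with an estimated correlation), and 8 genes were higher and 0 lower adjusted over the list alone. With the authors' processed values, which cover 13 members, it was 1.23, against 2.49 over 13 members with no detection filter beyond that of the authors.

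Of the 7 paternally expressed genes that fell in pNSC, 6 were higher again in miPS-NSC, against 155 of the 388 other genes that fell (39.9%, Fisher's exact test, two-sided, p = 0.02). Over all genes, 161 of the 395 genes lower in pNSC were higher in miPS-NSC, and 212 of the 533 higher ones were lower. Independent lists of these sizes would share 30.2 and 37.3 genes, but this value leaves out that both comparisons use the same pNSC arrays, so part of the excess can come from them. In 100 simulations of unchanged groups 0 genes were shared, which says little, since they held only 6 calls in all. Chromosome 4 gave 48 of the 161 genes, and without it, chosen after seeing the data, 113 of 283 lower genes were higher again (6 of 7 against 107 of 276 for the paternally expressed and the other genes, Fisher's exact test, two-sided, p = 0.0175). Both Fisher tests count genes as independent, though Snrpn, Mkrn3 and Ndn are neighbours in the Prader-Willi region, so their p-values may be too small. The tests also compare unlike falls. The 7 genes fell to below background, and Mest counted as higher again at 24.1% of its fNSC level. A gene that fell just 2-fold counts only after a nearly full return. The gene names also favour genes present in miPS-NSC or MEF. The 2 shares are therefore not directly comparable. The 15 maternally expressed genes did not pass the test as a list (median -0.197, or -0.099 at the bounds, adjusted p = 0.402). Among them Cdkn1c rose 7.41-fold and Pon2, a lactonase, fell 2.15-fold.

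Proliferation genes and neural stem cell markers were lower in miPS-NSC than in pNSC. Of 17 proliferation genes, 8 fell and 1 rose (camera adjusted p = 0.0117, and adjusted p = 0.307 with an estimated correlation). The replication helicase gene Mcm3 fell 3.04-fold and cyclin gene Ccnd1 2.62-fold, and so did the cell cycle inhibitor Cdkn1a (2.76-fold), while the inhibitor Cdkn2a rose at least 24.9-fold, with another probe at 3.32 on the log2 scale. Neural stem cell markers fell (4 lower and 1 higher of 18, median -0.889, adjusted p = 0.0305, and adjusted p = 0.307 with an estimated correlation), with Fabp7 down 5.55-fold, Hes5 2.42-fold and Nes, nestin, 2.05-fold, and Ncan, a proteoglycan, up 2.06-fold. Genes of neurons gave 3 higher and 2 lower of 7: the synaptic vesicle gene Syt1 rose at least 8.63-fold, Eno2 7.49-fold and Gad1 4.46-fold, whereas Syp fell 2.11-fold. Of 7 astrocyte genes, Slc1a2 rose 4.52-fold, Clu 2.19-fold, and Apoe fell 3.38-fold. Fibroblast genes gave 4 higher and 2 lower of 11, with Thy1 at least 11.5-fold and Twist1 at least 8.59-fold higher. Other rises were those of Fbln2 (at least 86.5-fold, the other probe at 3.52 on the log2 scale) and Selenbp1 (at least 31.6-fold). Other falls were those of Scara3 (at least 40.7-fold), Cyp7b1 (at least 29.3-fold), the mitochondrial genes Dnajc15 (at least 25.9-fold) and Slc25a20 (at least 38.2-fold, the other probe at -1.96 on the log2 scale), and Flot2, whose brighter probe was at least 64.5-fold lower and whose other probe, detected in miPS-NSC, was at -5.31 on the log2 scale.

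Xist, the RNA that coats the inactive X chromosome, was measured at 8.26 in pNSC and 8.15 in fNSC and fell at least 4.18-fold to below background in miPS-NSC. Hox genes Hoxa4, Hoxa5 and Hoxa7 fell at least 6.02-fold, 3.27-fold and at least 2.38-fold, Gbx2 rose 2.86-fold, and the 9 hindbrain and posterior genes had a median of 0.519 but a mean of -0.218 (adjusted p = 0.817). Pluripotency genes were not called as a list (2 of 6 higher, adjusted p = 0.0763), with Klf4 at least 2.71-fold and Klf2 2.36-fold higher. Dnmt3b rose 2.12-fold as the only called imprint regulator of 13, and of 3 oligodendrocyte lineage genes Pdgfra fell at least 24.5-fold and Cspg4 at least 1.69-fold. Calls in the other lists were 1 higher and 3 lower of 11 oxidative stress and glutathione genes, with Gstm5 at least 16.9-fold lower. There were also 1 higher and 2 lower of 7 interferon genes, 2 higher of 4 neural crest genes (Ets1, 4.3-fold) and 1 lower of 4 forebrain genes (Otx2). Of 7 MHC class I genes 1 was lower (Tap1), and Gata6 was lower by at least 1.82-fold. The lists other than paternally expressed, proliferation and neural stem cell genes did not pass camera (adjusted p between 0.0763 and 0.817). In total 1186 genes were called, 619 higher and 567 lower in miPS-NSC, and 121 of the higher ones lie on chromosome 4, Klf4 and Cdkn2a among them. Without chromosomes 4 and 19 these were 482 higher and 540 lower, which turns the majority around. The count was 596 with the authors' processed values.

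Compared with fNSC, the paternally expressed genes of miPS-NSC did not pass the test as a list (median 0.146, or 0.018 at the bounds, mean -0.082, adjusted p = 0.822), while 4 of them were called. In miPS-NSC, Snrpn was at 111% of its fNSC level, Mkrn3 at 88%, Nnat at 54.7% and Nap1l5 at 194%, and none of these was called. Impact was 2.67-fold higher (adjusted p = 7.22e-05) and Dlk1 at least 4.7-fold higher, while Mest was 4.15-fold lower and Ndn at least 10.4-fold lower. Adjusted over the list alone, 2 were higher and 2 lower. Of the 15 maternally expressed genes, Cdkn1c was 3.2-fold higher and 14 were not called (median -0.044, or -0.027 at the bounds, mean 0.015, adjusted p = 0.937). The sign of that median depended on the arrays, since it became 0.038 without miPS-NSC replicate 1.

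Astrocyte genes were higher and neural stem cell and proliferation genes lower in miPS-NSC than in fNSC. For the astrocyte list, 4 of 7 were higher, among them Clu (17.8-fold), Apoe (at least 10.6-fold) and Gja1 (9.36-fold), with a median of 1.47 and an adjusted p = 0.026 (0.212 with an estimated correlation). Neural stem cell markers gave 5 lower and 1 higher of 18 (median -0.463, adjusted p = 0.026, and 0.212 with an estimated correlation), with Hes5 6.59-fold, Notch1 2.63-fold and Nes 2.38-fold lower. Proliferation genes gave 2 lower and 1 higher of 17 (median -0.613, adjusted p = 0.00886, and 0.212 with an estimated correlation), namely Mcm3 (2.23-fold lower) and the inhibitors Cdkn1a (3.5-fold lower) and Cdkn2a (4.06-fold higher). Pluripotency genes passed too (2 of 6 higher, median 0.786, or 0.592 at the bounds, adjusted p = 0.026, and 0.212 with an estimated correlation), with all 6 fitted differences positive (0.612 to 1.14) and Fbxo15 (at least 1.48-fold) and Klf4 (2.04-fold) called. However, 3 of these 6 genes were not detected on both arrays of the dimmer group. The other 16 of the 22 list genes, Nanog, Sall4, Lin28a and Zfp42 among them, had no named probe that passed the filter. The list therefore says little about pluripotency. Imprint regulators passed as well (1 of 13 lower, Ctcfl, median -0.395, adjusted p = 0.0299, and 0.212 with an estimated correlation). Neuron genes did not pass as a list (3 higher and 1 lower of 7, adjusted p = 0.0569), but Eno2, which is also a glycolytic enzyme, rose 81.2-fold, Gad1 9.57-fold and Syt1 at least 8.02-fold.

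**Figure D2:**
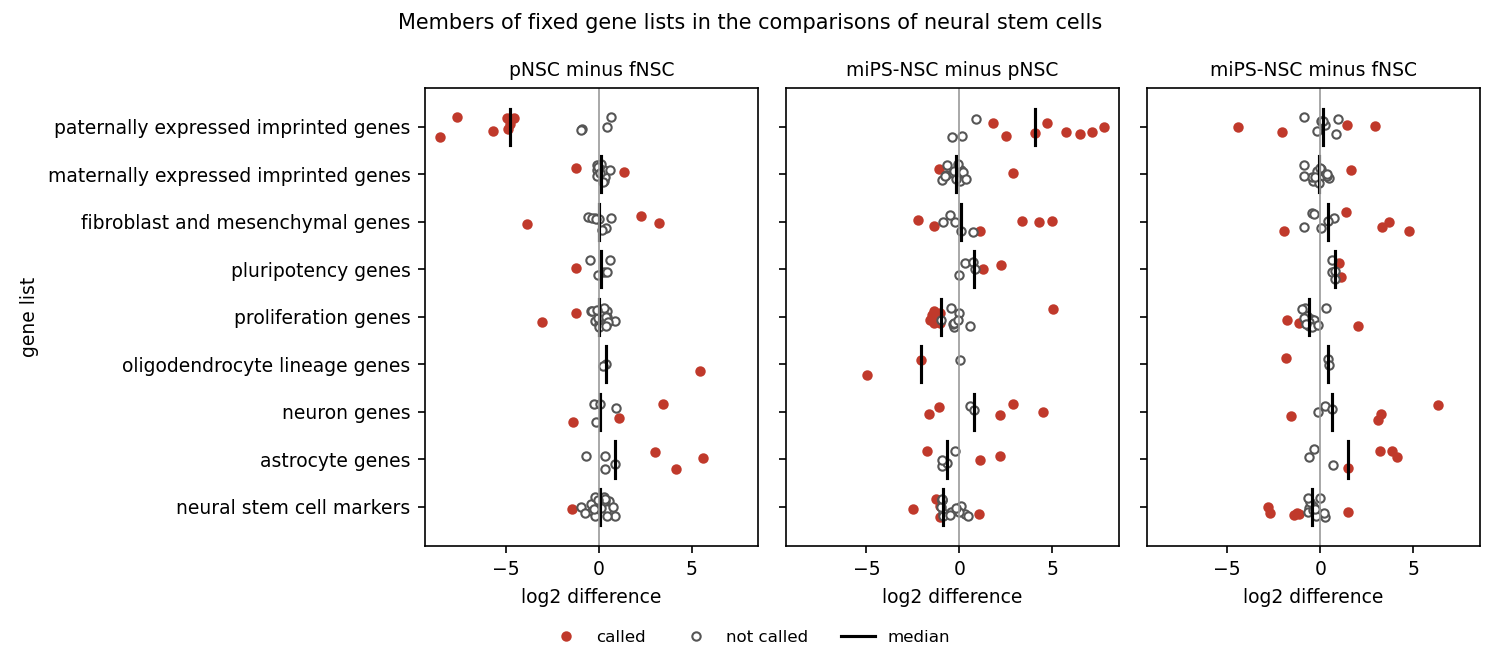
Log2 difference (horizontal axis) of the members of 9 gene lists (vertical axis) in the 3 comparisons of NSC groups, with filled points for called genes, open points for the others and a black bar at the median of the list. Paternally expressed genes have a median of -4.77 in pNSC against fNSC, 4.04 in miPS-NSC against pNSC and 0.146 in miPS-NSC against fNSC, while the medians of maternally expressed genes stay between -0.197 and 0.116.

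Other rises in miPS-NSC against fNSC were those of Anxa2 (49.3-fold), Nrn1 (40.6-fold), Fbln2 (38-fold) and Renbp (at least 28.6-fold). Falls were those of Vxn (at least 64.3-fold), Ddit4l (at least 45.6-fold), Mfsd2a (at least 32.3-fold), Sspn (at least 26.4-fold) and Dnajc15 (at least 24-fold). Thy1 and Mgp of the fibroblast list were at least 11.5-fold and at least 7.14-fold higher (4 higher and 1 lower of 11), and Acta2 3.79-fold lower, though its other probes lay between -0.991 and -0.098 on the log2 scale. Xist was at least 3.88-fold lower. Of 7 interferon response genes, Ifitm3 was 8.39-fold and Ifit2 2.12-fold lower, and 7 MHC class I genes gave 1 higher (H2-K1, an MHC class I chain, 2.99-fold) and 2 lower (Tap1 and Psmb9). Oxidative stress and glutathione genes gave 4 higher and 1 lower of 11, with Nqo1 up 2.91-fold and Gstm5 down at least 23.8-fold. Hindbrain genes gave 1 higher (En1, at least 5.24-fold) and 3 lower of 9. Cspg4 was the only called gene of 3 oligodendrocyte lineage genes (at least 1.43-fold lower) and Ets1 of 4 neural crest genes (2.16-fold higher), and none of 4 forebrain genes was called. None of these lists passed camera (adjusted p between 0.138 and 0.937). In the oligodendrocyte list, the interferon list and the list of oxidative stress and glutathione genes the median and the mean had opposite signs, as in maternally and paternally expressed genes. In MHC class I genes the median was -0.209 while the test pointed upward. Altogether 1144 genes were called, 689 higher and 455 lower, of which 43 lower ones, Acta2 and Ifit2 among them, lie on chromosome 19. The count was 566 with the authors' processed values.

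Genes of chromosomes 4 and 19 stood apart from those of the other chromosomes. This comparison was chosen after seeing the data and used 6707 genes detected on all 6 NSC arrays. In pNSC the 409 genes of chromosome 4 had a median log2 difference of -0.72 from fNSC, and 90.5% of them were lower (camera over 20 chromosomes, adjusted p = 9.72e-28, and adjusted p = 0.00159 with an estimated correlation). In miPS-NSC these genes were at 0.634 against pNSC and -0.052 against fNSC. The 256 genes of chromosome 19 were lower than in fNSC both in pNSC (median -0.489, adjusted p = 3.03e-12, and 0.00399 with an estimated correlation) and in miPS-NSC (-0.498, adjusted p = 2.65e-09, and 0.0131 with an estimated correlation). Medians of the other 18 chromosomes lay between -0.15 and 0.057 in the 3 comparisons.

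**Figure D3:**
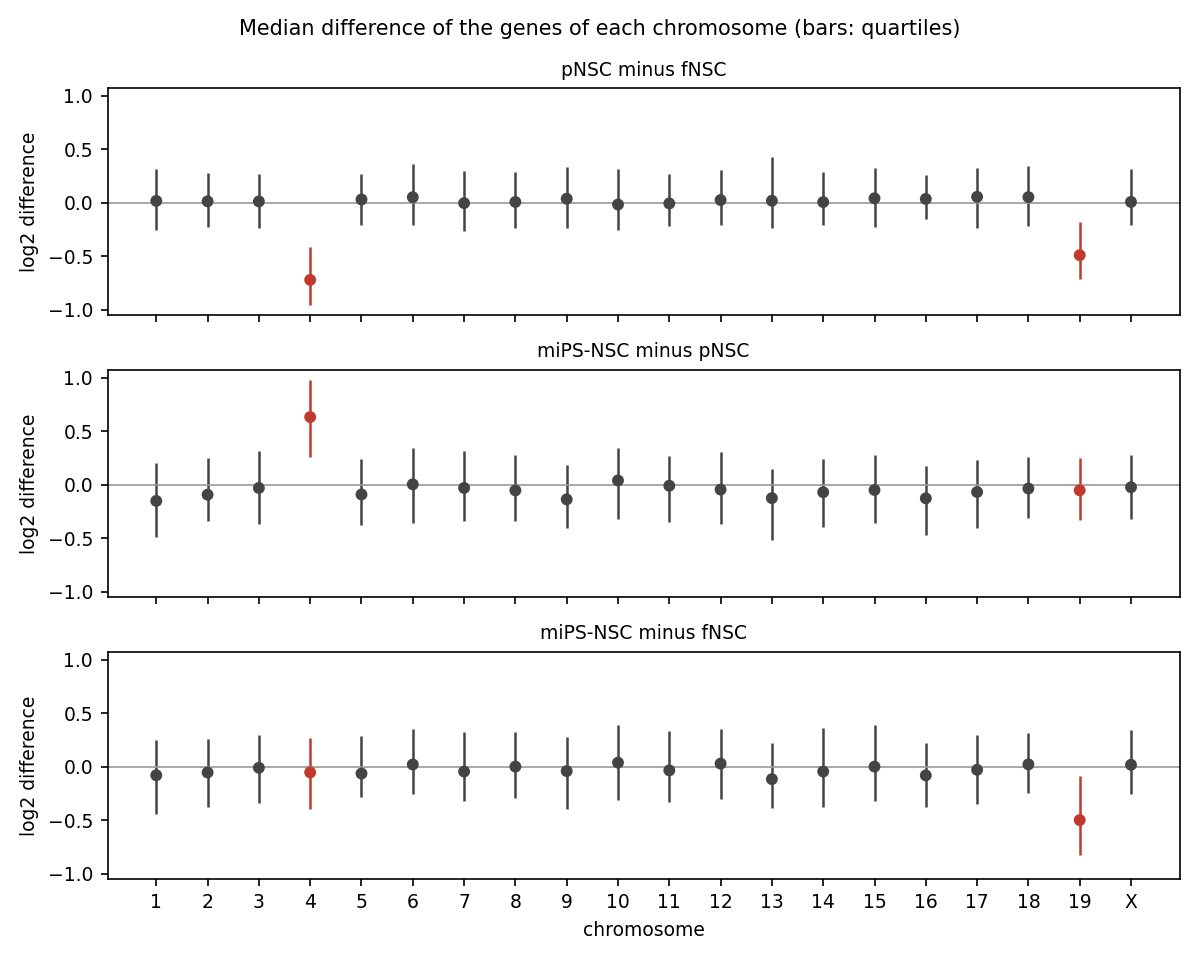
Median log2 difference (vertical axis) of the genes of each chromosome (horizontal axis), with lines from the lower to the upper quartile, in the 3 comparisons of NSC groups and with chromosomes 4 and 19 in red. Chromosome 4 lies at -0.72 in pNSC against fNSC and at 0.634 in miPS-NSC against pNSC, and chromosome 19 lies at -0.489 and -0.498 in the comparisons with fNSC.

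The comparison with MEF sets the NSC cultures against another cell type. Neural stem cell markers were higher in the NSC groups, with 14 of 18 up and 1 down (median 2.93, or 2.71 relative to the median of all genes, camera adjusted p = 0.00313, and adjusted p = 0.155 with an estimated correlation). The transcription factor Olig1 was at least 453-fold higher, the glutamate transporter Slc1a3 109-fold, and the proteoglycans Ncan and Bcan at least 75.3-fold and at least 53.4-fold. Aldoc, an astrocyte aldolase, was at least 174-fold higher, and Bcas1 and Nup210 at least 221-fold and at least 184-fold. All 11 measured fibroblast genes were lower (median -5.3, or -5.52 relative to all genes, adjusted p = 6.03e-07, and adjusted p = 0.0754 with an estimated correlation), with Acta2 lower by 287-fold and Thy1 by at least 205-fold, beside Thbs2 (at least 316-fold), Loxl1 (at least 235-fold) and Anxa3 (at least 353-fold). By group, all 11 fibroblast genes were called lower in fNSC and in pNSC, but 9 in miPS-NSC, where 2 were not called. Proliferation genes (12 higher and 1 lower of 17, camera adjusted p = 0.0281), forebrain genes (4 of 4 higher, adjusted p = 0.0474) and imprint regulators (9 of 13 higher, adjusted p = 0.0158) rose. Oxidative stress and glutathione genes fell (1 higher and 6 lower of 11, camera adjusted p = 0.0401). With an estimated correlation the adjusted p of these 4 lists was 0.255, 0.255, 0.193 and 0.244. Examples are Top2a (7.26-fold), Otx1 (at least 18.1-fold), Ezh2 (7.46-fold) and Uhrf1 (5.56-fold) upward, and Gstm2 downward by 34-fold. Of the forebrain genes, Otx2 was below background in fNSC, miPS-NSC and MEF. Taken group by group, forebrain genes passed against MEF in pNSC (adjusted p = 0.0273, and 0.222 with an estimated correlation) but not in fNSC (0.113) or miPS-NSC (0.0548). Oxidative stress and glutathione genes passed in fNSC (0.0135, and 0.166 with an estimated correlation) but not in pNSC (0.166) or miPS-NSC (0.0753). Whether the groups differ in this was not tested. Relative to the median of all genes, the medians of the 4 lists were 1.7, 2.64, 1.03 and -1.48. Many of these genes were below background in a group: at the bounds, the 3 NSC groups against MEF had medians of 1.3 to 2.64 for neural stem cell markers, 1.22 to 1.68 for forebrain genes and -5.19 to -4.87 for fibroblast genes.

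Imprinted genes differed from MEF in both directions in fNSC and miPS-NSC, while in pNSC no paternally expressed gene was called higher. Igf2 at 13.43 and Ndn at 13.54 in MEF were at least 149-fold and at least 74.4-fold lower in the mean of the NSC groups, and Igf2r and Cdkn1c were 6.58-fold and 12.1-fold lower, while Ppp1r9a was at least 18-fold higher. The paternally expressed list gave 4 higher and 5 lower of 11 and the maternally expressed list 4 higher and 3 lower of 15 (adjusted p = 0.501 and 0.713). Taken group by group, paternally expressed genes gave 0 higher and 9 lower in pNSC (median -4.26, or -3.17 at the bounds, adjusted p = 0.000131, and 0.0732 with an estimated correlation), and 5 higher and 4 lower both in fNSC (adjusted p = 0.995) and in miPS-NSC (0.762). The 9 lower in pNSC include Peg10, which was detected on no pNSC or MEF array, so its fall is not a measured one. They also include Nap1l5, which was detected on 1 MEF array. The list results for astrocyte genes (4 higher and 2 lower of 7), neuron genes (4 higher and 2 lower of 7), oligodendrocyte lineage genes (1 higher and 2 lower of 3), neural crest genes (1 higher and 1 lower of 4), hindbrain genes (5 higher and 3 lower of 9), pluripotency genes (1 higher and 2 lower of 6), interferon genes (1 higher and 5 lower of 7), MHC class I genes (2 higher and 2 lower of 7) and X inactivation genes (1 higher and 1 lower of 2) did not pass camera (adjusted p between 0.109 and 0.883), although interferon genes passed in miPS-NSC alone against MEF (adjusted p = 0.0351, and 0.225 with an estimated correlation). The median of maternally expressed genes was 0.01 (-0.211 relative to all genes) and that of X inactivation genes 0.35, while both tests pointed downward, and the median and the mean of MHC class I genes had opposite signs. Gata6 was lower by at least 3.84-fold. Although MEF are labelled female, Xist was below background on both MEF arrays (5.24), and Uty, a Y-linked gene, stood at 7.56 in MEF and below background in the NSC groups, at least 2.55-fold lower.

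Of the 8107 genes, 3369 were called between the NSC groups and MEF, 2000 higher and 1369 lower in NSCs. The median of all genes was shifted by 0.221 in this comparison and by 0.049 with the authors' processed values. Relative to the shift of 0.221, 1571 genes were higher and 1690 lower, so the majority changes side. Over all 12478 kept probes, named or not, 2916 were higher and 2661 lower. The count was 2022 with the authors' processed values.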

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

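The tests of a copy number change for chromosomes 4 and 19, the test of the labelled genotype, the test of an admixture of fNSC, and the comparison with random lists of dim genes were chosen after the results were seen. Probes without a gene name here, which the comparisons by gene do not use, were detected on both arrays of 1 group and on no array of another group in 24 cases for fNSC, 47 for pNSC, 81 for miPS-NSC and 712 for MEF.

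In pNSC, genes of chromosome 4 had a median log2 difference of -0.72 from fNSC. Against a bias of the normalization that depends on the signal, 0 of 10000 random gene lists with the same signals had a median as low, the lowest being -0.074. Against sequence variants under single probes, which would touch a minority of genes, 90.5% of the 409 genes were lower. Loss of 1 copy of the chromosome in part or all of the pNSC culture may explain the pattern. All 10 of the 10 segments in gene order were lower, with medians from -0.829 to -0.575, and these cells stood apart from MEF too (-0.725 relative to the other chromosomes). A full loss of 1 of 2 copies would give -1 without compensation. Relative to the other chromosomes, pNSC minus fNSC was -0.727, but -0.542 with quantile normalization without background correction and -0.572 with the authors' processed values. The size of the shift thus depends on the normalization, and its distance from -1 cannot be read as a copy ratio. The labelled genotype alone would leave pNSC and miPS-NSC alike, but these genes had a median of 0.634 in miPS-NSC against pNSC. DNA was not analysed here, so the loss stays a hypothesis, and other differences between the cultures, tied to the groups, stay open.

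Genes of chromosome 19 were higher in fNSC than in pNSC, by a median that reads -0.489 as pNSC minus fNSC, and relative to the other chromosomes stood 0.496 above MEF in fNSC but 0.036 in pNSC and 0.036 in miPS-NSC. A normalization bias was not borne out, as 0 of 10000 random lists with the same signals had as low a median, and neither were sequence variants, as 81.6% of the 256 genes were lower in pNSC. A gain of 1 copy in the fNSC culture may explain the pattern, with all 10 of the 10 segments shifted the same way, and 3 copies against 2 would give 0.585. The size again depends on the normalization. Relative to the other chromosomes, pNSC minus fNSC was -0.483, but -0.353 with quantile normalization without background correction and -0.364 with the authors' processed values. Genotype and culture, tied to the groups, stay open here.

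Of 7 paternally expressed genes that fell to below background in pNSC, 6 were high in miPS-NSC. The filter behind the gene names favours such genes, as a gene of fNSC silent in pNSC was mostly named only if miPS-NSC or MEF had it. An admixture of fNSC would bring back other transcripts that pNSC lacked, but 7 genes outside the imprinted lists, at least 8-fold lower and undetected in pNSC, stood at a median of at most 9.99% of their fNSC level in miPS-NSC, undetected genes being set at their background bound. Of these, 6 were undetected there and Serpinh1 stood at 208%, against a median of 88% (9.64% to 267%) for the 7 paternally expressed genes, Ndn at its bound. A general rise of dim genes was small: 498 other genes undetected in pNSC rose by a median of 0.475 on the log2 scale. Its 95% interval of 0.344 to 0.562 came from resampling genes and leaves out the spread between arrays. The bound of 0.5 set beforehand was met only within this interval, so it gives no verdict alone. The 10 paternally expressed genes undetected in pNSC rose by a median of 4.38, beyond the upper quartile of 1.111 of the 498 genes. Of 10000 random lists of dim genes 0 reached 4.38. The rise of the paternally expressed genes was known when these lists were chosen, so the draws restate it and are no separate test. A change of the imprinted state itself is a candidate explanation, and since DNA methylation was not analysed here, and miPS-NSC may also derive from other cells than these pNSC, it stays a hypothesis. The sample name pips-NSC of the miPS-NSC arrays bears on their origin, but it is not explained and does not settle it.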

How the results depend on the processing

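The alternatives that count without chromosomes 4 and 19 or over all kept probes were added after seeing the data; the others were fixed before. Where the cause of a change is not given, the cause was not tested. Counts of called genes, in the order pNSC against fNSC, miPS-NSC against pNSC, miPS-NSC against fNSC, and NSCs against MEF, were 412, 551, 521 and 1957 with quantile normalization without background correction, and 446, 596, 566 and 2022 with the authors' processed values. They were 419, 591, 565 and 1979 with only probes detected on all 8 arrays, which leaves out genes silent in a group, and 3652, 4187, 4163 and 6692 with no minimum fold. Over all kept probes the last count was 5577, as more features were tested. The counts stayed within 1.5 times of 928, 1186, 1144 and 3369 with median scaling, other detection thresholds, the mean of a gene's probes, the other fits, an adjusted p under 0.01, treat against 1.5-fold, and without chromosomes 4 and 19. The settings with detection p under 0.05 and with no filter covered 8571 and 8576 genes. Both hold only probes that passed the authors' filter, as other probes have no name, so their likeness was fixed in advance. Leaving out an array gave 927 to 974, 1181 to 1235, 1135 to 1196 and 3327 to 3387. A group with 1 array left was assumed to vary like the others. The array slide as a block was not run, as no slides were given in the sources used here.

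Paternally expressed genes were past the threshold in pNSC against fNSC and miPS-NSC against pNSC under each alternative that gave a value except camera with an estimated correlation (medians -4.771 with adjusted p = 0.103, and 4.043 with adjusted p = 0.1), and have no value with probes detected on all 8 arrays. Their medians were -2.408 and 1.84 with quantile normalization without background correction, and -2.405 and 1.227 with the authors' processed values, which cover 13 list members against 11. Over 13 members as well, they were -4.549 and 2.487 both with detection p under 0.05 and with no filter beyond that of the authors, which are nearly the same setting. Leaving out an array gave medians of -4.851 to -4.661 and 3.861 to 4.225, and 0.041 to 0.164 in miPS-NSC against fNSC. Maternally expressed genes gave 0.106 to 0.246, -0.443 to -0.056, and -0.087 to 0.038 in the same order. In miPS-NSC against fNSC their median of -0.044 turned to 0.038 without miPS-NSC replicate 1 and to 0.005 with probes detected on all 8 arrays, never past the threshold. Calls among the other lists numbered 14, against 9 with probes detected on all 8 arrays, 0 with an estimated correlation, and 12 to 17 when an array was left out. Of paternally expressed genes, 6 were lower in pNSC and higher again in miPS-NSC (6 to 8 when an array was left out), and 0 with probes detected on all 8 arrays, which removes these genes by construction.

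The distances between fNSC and pNSC, pNSC and miPS-NSC, and fNSC and miPS-NSC were 0.521, 0.581 and 0.575 with quantile normalization without background correction, 0.528, 0.587 and 0.581 with the authors' processed values, 0.602, 0.677 and 0.692 with probes detected on all 8 arrays, 0.805, 0.872 and 0.875 with the mean of a gene's probes, and 0.805, 0.875 and 0.872 both with detection p under 0.05 and with no filter. Among named genes, 4128 values under the alternatives kept their direction and side of the threshold, 125 fell short of it, 52 of these under quantile normalization without background correction and 49 under the authors' processed values, 5 newly passed, and 7 changed sign. These 7 values belong to Igf2r, Ndn and Uty where they were not called. Leaving out an array gave -0.052 (without fNSC replicate 2) to 0.283 for Igf2r in pNSC against fNSC, -0.345 to 0.038 (without miPS-NSC replicate 1) and 0.014 (without fNSC replicate 1) for Igf2r in miPS-NSC against fNSC, -0.012 (without miPS-NSC replicate 2) to 0.301 for Ndn in miPS-NSC against pNSC, -0.135 (without miPS-NSC replicate 1) to 0.516 for Uty in miPS-NSC against pNSC, and -0.434 to 0.217 (without miPS-NSC replicate 2) and 0.002 (without fNSC replicate 1) for Uty in miPS-NSC against fNSC. A signal under the background of an array limits how small a level, and how large a fall, can be measured.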

Other observations

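A set of genes was detected in every group but miPS-NSC. These genes were chosen after their values were seen. On neither miPS-NSC array but on all 6 others, 59 genes were detected, and 8 of them were at least 8-fold below every other group when set at their background bound, against 36 and 4 for pNSC and 74 and 0 for fNSC. Those of miPS-NSC include the glutathione transferase Gstm5, the mitochondrial genes Dnajc15 and Slc25a20, the sugar transporter Slc50a1 and the transcription factor Zic1. Genes with a fitted change of at least 8-fold had 16 other probes in pNSC against fNSC, 27 in miPS-NSC against pNSC and 27 in miPS-NSC against fNSC. Of these, 15, 26 and 24 changed by at least 2-fold the same way, and 1 in miPS-NSC against fNSC had the opposite sign, with no minimum fold asked.

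Some genes detected in fNSC were undetected in both pNSC and miPS-NSC. Of the 7 genes outside the imprinted lists that were at least 8-fold lower and undetected in pNSC, 6 were also undetected in miPS-NSC, as Ndn was, namely Sspn, Cpq, Nlrx1, Cldn12, Rpusd4 and Npepl1, while Serpinh1 was detected in miPS-NSC. These genes were chosen after their values were seen. Genes of the X chromosome showed a median log2 difference of 0.009 in pNSC against fNSC, -0.022 in miPS-NSC against pNSC and 0.019 in miPS-NSC against fNSC, although Xist fell to below background in miPS-NSC.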
